A study of Rattus norvegicus with 4 samples.

How the data were processed

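The 4 samples were cultures of the rat alveolar macrophage line NR8383 at 20 passages, grown for 48 h in 25 cm2 flasks and exposed to nanotubes for 4 h. Per the labels' protocols, 100 ng of total RNA with an integrity number above 7.5 was labelled with Cy3 and hybridised as 1 colour to Agilent arrays. The group and the replicate number of every sample came from its title. The cultures without nanotubes that the study describes were not analysed here, and no comparison between groups was possible.

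The deposited files are scanner output with spot intensity on a linear scale, per the file headers. The processed signal column is the intensity after the background subtraction of Agilent Feature Extraction version 11.0.1.1, per the submitters' processing notes, with no scaling between arrays. The median signal and median background intensity columns are deposited without that subtraction and were used for 1 alternative. Flags for well above background, saturation, non-uniform spots and population outliers were used as the software wrote them.

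The 4259 control spots were left out, as were spots that the software called non-uniform or population outliers on that array (596, 546, 560 and 1296 gene spots on replicates 1 to 4). The log2 processed signals of the spots of a probe were averaged. A probe was called on an array when over 50% of its remaining spots were well above background, and it was detected when called on all 4 arrays. As under 50% of probes were detected, each array was scaled by the 75th percentile over detected probes. The plan, lists and rules fixed before the data were examined named the percentile of the array and kept all spots. Both changes were made after the data were seen, and the percentile over all gene probes and the inclusion of all spots were run as added alternatives. For a gene with several detected probes, the probe with the highest mean level gave the value. Where probes of a gene disagreed, the gene was not above background only if all its probes were.

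The files hold transcript accessions but no gene names. Accessions without versions were matched to the RefSeq gene table of assembly GRCr8, which named 21109 of 45598 probes (46.3%) and 16581 genes. The other 24489 probes, of which 6958 carry Ensembl transcript names, were counted without a name. The build named in the file headers is older than that assembly, so no coordinates are printed.

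Detection in each of 21 gene lists was counted and compared with all named genes measured on all arrays by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. This test was added after the data were seen. The lists cover macrophage identity, cytokines, NF-kB, inflammasome, uptake receptors, antioxidant, metal, heat shock, p53, cell cycle, lysosome, sterol, matrix, immediate early, interferon and reference genes, and markers of lung epithelium, fibroblasts, endothelium, lymphocytes and granulocytes. Lists with 3 or more detected members were set against 10000 random lists of the same size, drawn from 20 bins of mean level, as a description with no p-value. Random lists treat genes as independent. Probes with at least 3 spots on each array were tested for differences between arrays with the moderated F test of limma version 3.58.1 in R version 4.3.3 (Benjamini-Hochberg adjusted p below 0.05). Its residual is the noise between spots of an array, so it does not measure the spread between cultures. Python version 3.11.15, numpy version 2.4.6, pandas version 2.3.3 and scipy version 1.17.1 did the rest.

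The named genes followed a rule fixed in advance. It took, per list in its written order, the first 2 detected genes and the first 1 not above background on any array, with 4 and 2 for the macrophage, cytokine and antioxidant lists. It added the 12 detected genes and the 10 detected list members with the largest SD. Fewer were named where a list had fewer, and a gene left out of the text was not replaced.

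Both procedures were tested on simulated data. For the comparison of the 4 arrays over spots, 1350 probes were simulated from the real levels and spot noise with 200 probes changed on 1 array. The test called 40% of those changed by 0.25 on the log2 scale, 72% at 0.5, 94% at 1 and 100% at 1.5, with 50 probes per size, and 10 of 1150 unchanged probes. For the list deviations, 200 unchanged lists of 6 among 1946 simulated genes gave 5.5% of 800 pairs outside the central 95%, and 82% of lists lowered by 0.5 on 1 array were found. The simulated genes were independent, which real genes are not. The simulated spots also held no shift shared by a whole array, so the 10 calls among unchanged probes give no error rate for arrays with such shifts.

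The alternatives were another detection rule (above the 95th percentile of negative control spots plus 10%), detection on at least 3 of 4 arrays, quantile normalization, no scaling, normexp background correction with an offset of 50, no filter on dim probes, bright genes only, the mean of a gene's probes, a loess surface over the array removed, and each replicate left out in turn. The normexp alternative used the median signal, in place of the mean signal that had been planned. Genes with a probe printed 10 times were added as an alternative after the data were seen. The number of arrays and the signal above background, not a count of reads, set the precision.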

Results

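The arrays measured messenger RNA in NR8383 cells, a macrophage line grown from cells washed out of the lung of a normal rat. All 4 samples were cultures exposed for 4 h to NRCWE006, a multi-walled carbon nanotube (a fibre-like particle of rolled carbon sheets), at a dose of 1 cm2 of particle surface per cm2 of culture. They form 1 group with 4 biological replicates, numbered 1 to 4 by the labels. The study also describes cultures without nanotubes, which were not analysed here, so no value below is an effect of the exposure. The design leaves 2 questions: which transcripts were measurable in the exposed cells, and how far the 4 cultures differed from each other.

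Each sample was hybridised to 1 array with 58717 gene spots, which belong to 45598 probes. Of these probes, 43279 were printed once, 969 were printed 2 times and 1350 were printed 10 times. Probes well above background numbered 5722, 4745, 4252 and 6476 on replicates 1 to 4. No gene spot was saturated. The 75th percentile of the signal of probes detected on all arrays was 384, 281, 236 and 223. The number of arrays limits the precision of every value. All levels below are log2 values relative to that percentile of the same array, given as mean ± SD over 4 arrays, and levels of different probes are not comparable with each other.

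Reference, heat shock, lysosome, antioxidant and macrophage identity genes were well above background more often than named genes in general, in 80.0%, 61.1%, 52.9%, 47.8% and 33.3% of cases. Of the markers of fibroblasts, lymphocytes and granulocytes, none was well above background on all arrays, but these short lists did not differ from named genes in general by test. In all, 3208 probes (7.04%) were well above background on all 4 arrays, 5773 on 1 to 3 arrays and 36617 (80.3%) on none. They named 1946 genes, or 11.9% of the 16419 named genes measured on all arrays. Of 340 genes with a probe in 21 fixed lists, 86 were detected. Compared with all named genes, the share detected was higher in 5 lists by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists.

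**Figure D1:**
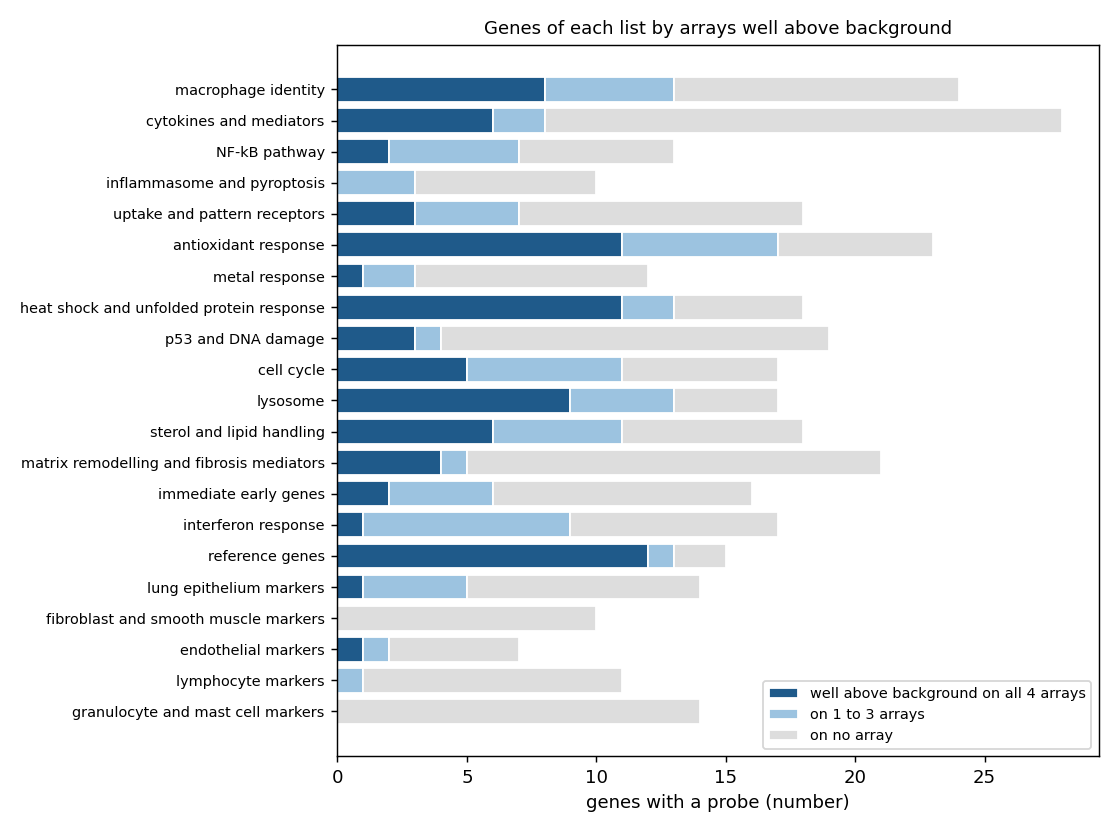
Number of genes with a probe in each of 21 lists (horizontal axis), divided into genes well above background on all 4 arrays, on 1 to 3 arrays and on no array. Reference genes (12 of 15), heat shock and unfolded protein response genes (11 of 18) and lysosome genes (9 of 17) were mostly detected, and 0 of 10 fibroblast and smooth muscle markers were.

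Macrophage identity genes were detected in 8 of 24 cases (33.3%, adjusted p = 0.0206 by Fisher's exact test). The first 4 by the fixed order were Cd68, a lysosomal glycoprotein of phagocytes, Fcgr1a, a high-affinity receptor for immunoglobulin G, Lyz2, the macrophage lysozyme, and Spi1, the transcription factor PU.1. Their levels were -3.53 ± 0.61 for Cd68, -0.71 ± 0.15 for Fcgr1a, 2.5 ± 0.11 for Lyz2 and -3.14 ± 0.73 for Spi1 (SD, n = 4). Mrc1, the mannose receptor, and Csf1r, the receptor of macrophage colony-stimulating factor, were not well above background on any array. In all, 11 genes of this list were not.

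Of the cytokines and mediators, 6 of 28 were detected (adjusted p = 0.355 by Fisher's exact test). Tnf, encoding tumour necrosis factor, had a level of -2.73 ± 0.28, and the chemokine genes had levels of -1.81 ± 1.13 for Ccl2, 0.23 ± 0.19 for Ccl3 and -2.02 ± 0.28 for Ccl4 (SD, n = 4). Il1b and Il6, encoding the inflammatory cytokines interleukin 1 beta and interleukin 6, were among 20 genes of the list not well above background on any array. In the NF-kB pathway list, 2 of 13 genes were detected (adjusted p = 0.797 by Fisher's exact test over the 12 measured on all arrays). They were Nfkbia, which encodes an inhibitor of NF-kB, at -2.33 ± 0.27 and Icam1, an adhesion molecule, at -1.22 ± 0.27 (SD, n = 4). Nfkb1 was not well above background. None of the 10 inflammasome and pyroptosis genes was detected (adjusted p = 0.797 by Fisher's exact test), and Casp1, the protease that activates interleukin 1 beta, was not well above background on any array. Of the interferon response list, 1 of 17 genes was detected, Stat2, a signal transducer of type I interferon, at -2.71 ± 0.25 (SD, n = 4). Irf7 was not well above background. The immediate early genes had 2 of 16 detected, the transcription factor Jun at -3.04 ± 0.16 and Ier2 at -2.61 ± 0.21 (SD, n = 4), and Fos was not well above background.

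Antioxidant genes were detected in 11 of 23 cases (47.8%, adjusted p = 0.00015 by Fisher's exact test). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, had a level of -0.26 ± 0.54, Srxn1, encoding sulfiredoxin, -0.34 ± 0.25, Nfe2l2, the transcription factor NRF2, -2.44 ± 0.32, and Prdx1, a peroxidase, -1.11 ± 0.24 (SD, n = 4). Nqo1 and Gclm, both textbook targets of NRF2, were not well above background on any array. Of 12 metal response genes, only the metallothionein gene Mt1 was detected, at -1.28 ± 0.09 (SD, n = 4), and Mt2A was not well above background.

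Heat shock and unfolded protein response genes were detected in 11 of 18 cases (61.1%, adjusted p = 9.5e-06 by Fisher's exact test). The chaperone genes Hspa8 and Hsp90aa1 had levels of 2.84 ± 0.14 and -1.65 ± 0.26 (SD, n = 4), while the stress-inducible Hspa1a was not well above background. Lysosome genes were detected in 9 of 17 cases (52.9%, adjusted p = 0.00024 by Fisher's exact test), with levels of -1.72 ± 0.17 for Lamp1 and -1.70 ± 0.11 for Lamp2, both membrane proteins of the lysosome (SD, n = 4). The protease gene Ctsl was not well above background. Sterol and lipid handling genes were detected in 6 of 18 cases (adjusted p = 0.0506 by Fisher's exact test), among them Srebf2, a regulator of sterol synthesis, at -2.24 ± 0.19 and the sterol exporter gene Abcg1 at 1.11 ± 0.32 (SD, n = 4). Among receptors for uptake and pattern recognition, 3 of 18 were detected, including the scavenger receptor gene Cd36 at -2.59 ± 0.44 and the beta-glucan receptor gene Clec7a at -1.13 ± 0.29 (SD, n = 4), while Msr1 was not well above background.

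The cell cycle list had 5 of 17 genes detected (adjusted p = 0.127 by Fisher's exact test), among them Cdk1, the kinase that drives entry into mitosis, at 0.05 ± 0.73 and Mcm2, a subunit of the replicative helicase, at 0.42 ± 0.13 (SD, n = 4), while Mki67 was not well above background. Of the p53 and DNA damage list, 3 of 19 genes were detected, and the 18 measured on all arrays entered the test. Cdkn1a, an inhibitor of cyclin-dependent kinases, lay at -0.07 ± 0.66 and the pro-apoptotic Bax at -1.45 ± 0.54 (SD, n = 4). Mdm2 was not well above background. Matrix remodelling and fibrosis mediators had 4 of 21 detected, including Tgfb1, transforming growth factor beta 1, at -2.69 ± 0.62 and the protease inhibitor gene Timp2 at 2.26 ± 0.09 (SD, n = 4), and the gelatinase gene Mmp9 was not well above background. Reference genes were detected in 12 of 15 cases (80.0%, adjusted p = 5.0e-08 by Fisher's exact test), with Actb at 4.11 ± 0.22 and Gapdh at 3.90 ± 0.31 (SD, n = 4). Tbp was not well above background.

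Few markers of other cell types were detected, but none of these lists was set apart from the 11.9% of all named genes by Fisher's exact test. Of 14 lung epithelium markers, 1 was detected, Napsa, an aspartic protease, at 0.01 ± 0.12 (SD, n = 4), while the surfactant gene Sftpc was not well above background. Of 7 endothelial markers, 1 was detected, Vwf, encoding von Willebrand factor, at -2.11 ± 0.44 (SD, n = 4), while Pecam1 was not well above background. None of 10 fibroblast and smooth muscle markers, 11 lymphocyte markers and 14 granulocyte and mast cell markers was detected, and Col1a1, Cd3e and S100a8 were not well above background on any array. The adjusted p of every list with no value printed above lay between 0.707 and 1.0 by Fisher's exact test.

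Being called not well above background is a limit of the arrays, not a level of 0. Of 581 detected genes with 2 or more probes, 272 had another probe that was not well above background on any array. With detection set by negative control spots instead, the count of probes well above background on all 4 arrays was 5991, and 136 list genes were detected.

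The second question was how far the 4 cultures differed, each measured on 1 array. In replicate 4, Cdk1 was lower than on the other arrays and Cdkn1a and Ccl2 were higher, each measured by a probe printed 10 times on every array. Cdk1 levels were 0.37, 0.37, 0.49 and -1.05 in replicates 1 to 4. Those of Cdkn1a were -0.50, -0.39, -0.30 and 0.91, and those of Ccl2 were -2.53, -2.73, -1.74 and -0.24. The moderated F test over arrays in limma, with the spots of each array as repeats, gave adjusted p = 4.0e-21 for Cdk1, 3.9e-20 for Cdkn1a and 3.3e-20 for Ccl2. The mitotic kinase gene Plk1 had -1.63, -1.58, -1.73 and -2.77 (adjusted p = 2.9e-10, limma).

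**Figure D2:**
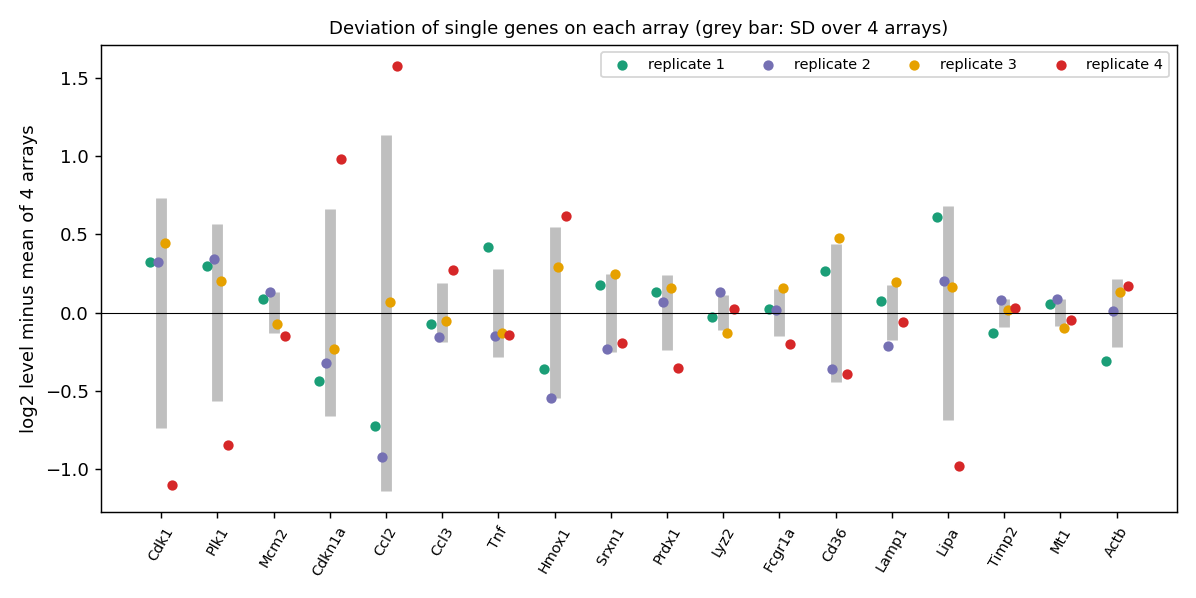
Deviation of the log2 level of single genes from the mean of 4 arrays (vertical axis), with 1 point per replicate and a grey bar of 1 SD over the 4 arrays to each side of 0. Replicate 4 lies lowest for Cdk1 and Plk1 and highest for Cdkn1a and Ccl2, while Mt1 has an SD of 0.09 and Timp2 an SD of 0.09.

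In this test, 1093 of 1350 probes printed 10 times differed between arrays. This count includes probes at background, which also differ between arrays after scaling. The median negative control signal was 3.36, 2.98, 3.30 and 4.61 on replicates 1 to 4. The 75th percentile used for scaling was 384, 281, 236 and 223, so the 2 did not move together. Among the 709 of the 1350 probes that were well above background on all arrays, 525 differed, and 35 also ranged over more than 2-fold. The 35 were 9 without replicate 4, 94 after quantile normalization, 281 without scaling, 699 when scaled by all gene probes and 5 with normexp. Mcm2, Prdx1, Cd36, Lyz2, Timp2, Mt1 and Actb also passed, with SDs over the 4 arrays between 0.09 for Timp2 and Mt1 and 0.44 for Cd36 and adjusted p between 5.0e-09 and 0.0473 in limma. Each culture had 1 array. The test thus compares arrays and not conditions, and it cannot tell the RNA of a culture from its labelling or hybridisation. Small shifts shared by all spots of an array also enter it, so its count depends on how the arrays are scaled.

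Replicate 4 was also compared relative to the median of all detected genes. This median lay at -0.07 against the mean of the other 3 arrays, and at -1.64 when scaled by all gene probes, -0.26 after quantile normalization, -0.47 without scaling and 0.08 after the normexp background correction. Scaling by all gene probes or not at all shifts every gene of an array alike, so values relative to this median test only quantile normalization and normexp. Cdk1 lay at -1.39 relative to it, and at -1.21 and -1.15 in those alternatives. Cdkn1a lay at 1.38 and at 1.57 and 1.01. Ccl2 lay at 2.17 and at 2.29 and 1.36, and Plk1 at -1.05 and at -1.52 and -0.41. Scaled by all gene probes, the Cdkn1a level was lower in replicate 4 (-0.26). The 75th percentile over all gene probes was a signal of 5.85, 3.82, 4.07 and 10.1 on replicates 1 to 4. The 95th percentile of negative control spots was 4.00, 3.48, 3.99 and 5.10. This scaling thus follows signal near background, and the value of -0.26 cannot be read as less Cdkn1a RNA.

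The median SD over 4 arrays was 0.241 on the log2 scale, with 0.102 and 0.519 as its 10th and 90th percentiles over 1946 genes. Pearson's r across genes, which are not independent replicates, lay between 0.975 and 0.981 among replicates 1 to 3 and between 0.924 and 0.936 for the pairs with replicate 4, with a median of 0.956. Between the highest and lowest replicate, 297 genes (15.3%) ranged over more than 2-fold. Replicate 4 was the highest in 171 of them and the lowest in 97. The count of genes over 2-fold between highest and lowest replicate was 90 without replicate 4. It depended on the processing, with 542 after quantile normalization and 39 with normexp. Normexp kept the scaling by detected probes, and its offset of 50 shrinks log2 differences, most of all for dim signals.

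The 12 genes with the largest SD were Mitf, Arl8a, Fam3c, N4bp3, Lsm7, Pwwp2b, Pigr, Osgep, Lrrc45, Palm, Ppp1r10 and Ccl2, and all except Ccl2 rested on a single spot per array. Mitf, a transcription factor of pigment cells and macrophages, had an SD of 1.73 with -3.86, -3.79, -3.15 and -0.19 in replicates 1 to 4. Arl8a, a lysosomal small GTPase, had an SD of 1.69, Fam3c 1.66, N4bp3 1.55, Pwwp2b 1.42, Pigr, the polymeric immunoglobulin receptor, 1.37, Osgep 1.37 and Lrrc45 1.26. All of these were highest in replicate 4. Signals on replicates 1 to 4 were 26.5, 20.3, 26.6 and 195 for Mitf and 17.8, 14.9, 18.4 and 129 for Arl8a. Replicate 4 also had the most probes well above background on 1 array alone, given below. Whether these high values share that source was not tested. Mitf, N4bp3, Pwwp2b and Pigr had 2 probes each, of which 1 gave the value. Lsm7 was highest in replicate 3 (SD 1.44) and Palm in replicate 2 (SD 1.24). Ppp1r10, with -0.54, -0.77, -2.50 and 0.40 in replicates 1 to 4, had its largest gap below the other arrays in replicate 3 (SD 1.21). Within the lists, the largest SDs were those of Ccl2 (1.13), Cdk1 (0.73), Spi1 (0.73), the oxysterol receptor gene Nr1h2 (0.73), the lysosomal acid lipase gene Lipa (0.68), Cdkn1a (0.66), Tgfb1 (0.62), the lipid droplet gene Plin2 (0.61), Cd68 (0.61) and Plk1 (0.56). Cdk1, Lipa and Plk1 were lowest in replicate 4, Nr1h2 was lowest in replicate 3, and the others were highest in replicate 4.

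**Figure D3:**
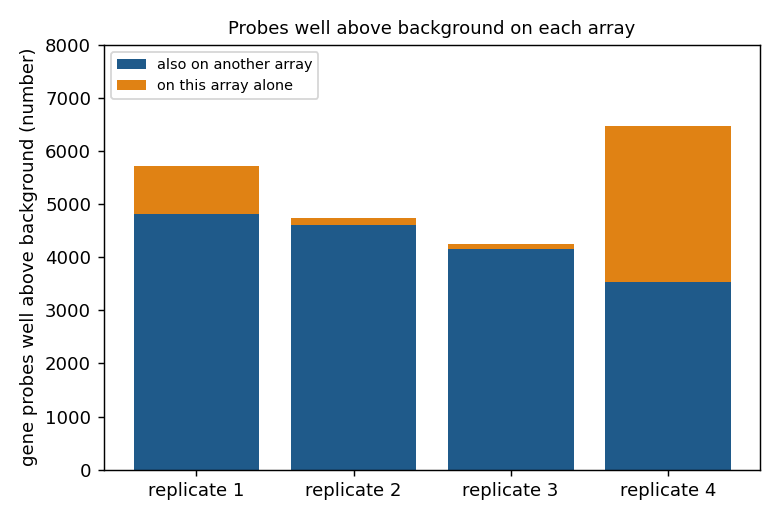
Number of gene probes well above background on each array (vertical axis), with the part found on that array alone. The part found on 1 array alone was 918, 145, 96 and 2952 probes for replicates 1 to 4.

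Replicate 4 stood apart as an array. It had 2952 probes well above background on no other array and missed 764 that the other 3 had, and 656 of its gene spots were called non-uniform against 17, 9 and 34 on replicates 1 to 3. The median signal of its negative control spots was 4.61, against 3.36, 2.98 and 3.30. All arrays were on 1 slide with 1 scan time, so neither could be tested as a batch.

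The spread and deviation of gene groups were set against those of random genes of like level. In the main setting, none of the 11 lists with 3 or more detected members had a median SD outside the central 95% of 10000 random lists matched on level. Under several alternatives, given in the section on processing, some lists lay outside it. The nearest were the reference genes, with a median SD of 0.256 at percentile 97.3, and the p53 and DNA damage list, with 0.538 at percentile 97.0. Of 44 pairs of a list and an array, 5 had a mean deviation outside that range, where 2.2 were expected by chance. Cytokines and mediators deviated by -0.38 from the mean of 4 arrays in replicate 2 (0 of 6 genes above their mean, percentile 0.03). Relative to random lists this was -0.36, and -0.23 without replicate 4 (percentile 0.48), the array on which Ccl2 was highest. Tnf levels were -2.31, -2.88, -2.86 and -2.87, so replicate 2 did not stand apart in that gene. Cell cycle genes deviated by -0.52 in replicate 4 (0 of 5 above, percentile 0.38), against -0.12 for random lists, and by 0.22 in replicate 2 (5 of 5 above, percentile 99.7). Among these 5 genes, the mean in replicate 4 rested mostly on Cdk1 and Plk1. The helicase subunit genes Mcm2, Mcm3 and Mcm7, of which Mcm3 and Mcm7 are named after their values were seen, lay nearer to the random value. Members had to be detected on all 4 arrays, so those not detected on replicate 4 could not enter this mean. Without replicate 4, 10 members were detected in place of 5, and 2459 named genes in place of 1946. Antioxidant genes deviated by 0.15 in replicate 3 (9 of 11 above, percentile 98.2). Sterol and lipid genes deviated by -0.21 in replicate 3 (1 of 6 above, percentile 2.0). This pair moved inside the central 95% after quantile normalization (percentile 3.6), with normexp (3.2), with all spots kept (2.7) and without replicate 1 (4.2). It stayed outside without replicate 4 (0.85). Without replicate 4, the cell cycle deviation in replicate 2 relative to random lists was 0.04 over 10 detected genes, rather than 0.20 over 5. These deviations keep the scale of the array: scaled by all gene probes, the mean deviation of the cytokine list was 0.18 and that of the sterol list 0.00365, and without scaling that of the antioxidant list was -0.07, while values relative to random lists cannot change under these scalings.

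For 235 genes with 2 or more detected probes, the deviations of 2 probes over the arrays had a median r of 0.502, and 69.4% of the pairs were above 0. Random pairs of probes of different genes had a median of -0.006 and 49.7% above 0.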

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

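The tests of additional spots on probes printed 10 times, of patches of the array, of bright neighbours, of negative control spots, of olfactory receptor probes and of the number of list and array pairs were chosen after the results were seen, as were the intervals of medians.

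Replicate 4 lay far from the other 3 arrays in 656 non-uniform gene spots, against 9 to 34 elsewhere, and in 764 probes that only it lacked, against 9 to 128. These were 2 of 8 array measures examined by the gap to the nearest other array. The same examination of 51 named genes found 9, with replicate 4 apart in 7. Chance gives about 5%, but 15 of the 51 were named only for a large SD, so their count is not set against it. Over all 1946 detected genes, which are not independent, 149 (7.66%) had an array apart, and it was replicate 4 in 103. Replicate 4 lay at -2.05 for Spi1, -1.47 for Prdx1, 0.91 for Cdkn1a, -1.05 for Cdk1, -0.93 for Pwwp2b, -1.34 for Lrrc45 and -2.77 for Plk1. Replicate 1 lay at -2.31 for Tnf and replicate 3 at 1.00 for Lsm7. Among control spots, 86 spots of ERCC probes, which have no rat target, were well above background on replicate 4 alone, and 0 on each other array alone. Of 35 spots of the adenovirus E1A control probe a104, 18 were well above background on replicate 4 and 0 on the others.

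For the 2952 probes well above background on replicate 4 alone, higher abundance of their transcripts in culture 4, as the whole source, would light the spots of a probe together, but only a share of 0.157 of such spots on probes printed 10 times fell on probes with most spots lit, and 27 genes seen by a second, detected probe had a median deviation of -0.098 there (95% bootstrap interval -0.305 to 0.0776). The spots did gather on probes, since 244 of 408 probes printed 10 times and dim elsewhere had no lit spot. If spots were lit independently, 184 were expected. Signal that depends on the probe would gather spots as well. Higher abundance as a part of the source thus stays open, but the gathering does not favour it. Olfactory receptor probes dim elsewhere were lit on replicate 4 in 7.09% of cases and other named probes in 7.66%, against 0.469% and 3.75% on replicate 1. A patch of the array is argued against by the share of 0.297 in the densest 8 of 32 blocks (0.25 if even), and spill from bright neighbours by a ratio of rates of 0.940. For extra signal on spots whatever their probe, the test set beforehand was the rate of lit ERCC spots. At 0.399 times the rate of gene spots it lay between its bounds and was undecided. Negative control spots, looked at afterwards, were lit in 0 of 276 cases. With spots taken as independent, this allows at most 0.146 times the rate of gene spots. It argues against extra signal that reaches negative control spots as often as gene spots. Signal that depends on the probe stays open.

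The second pattern is the lower level of cell cycle genes in replicate 4. Of the 45 replicate 4 spots of the 5 genes, 95.6% lay below the median of the same probe elsewhere, so the low mean did not rest on a few spots. This share cannot decide on spot errors, as the list was picked for its low mean and no share of other genes was counted. Random genes on probes printed 10 times had a median of -0.21 there. Scaling is argued against by a percentile of 0.51 after quantile normalization, the only scaling used that is not one factor per array. With normexp, which changes the background but keeps such a factor, the percentile was 0.35. A lower share of dividing cells in culture 4 may contribute. Deviations of second lists are medians against the mean of the other arrays. They are not on the scale of the fixed lists, whose values are mean deviations from the mean of 4 arrays. A second list of proliferation genes had a median deviation of -0.17 there over 17 detected genes, 14 of them lower, against -0.14 for random lists. Its percentile of 43.4 among random lists was past the bound of 10 set beforehand against this explanation, and it is left open only because the interval of the median (-0.56 to -0.06), added after that value was seen, includes the -0.2 the explanation needs. The 7 of its genes on probes printed 10 times were all lower, with a median of -0.39 against -0.21 for random genes on such probes (percentile 16.4), a subset looked at afterwards. Proliferation genes not detected on replicate 4 could not enter the second list, so a loss of such genes would not show in it. Differences in RNA or labelling of sample 4 were not tested.

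The third pattern is the deviation of the cytokine and mediator list from the 4-array mean in replicate 2. Scaling is argued against by a percentile of 0.06 after quantile normalization alone. Normexp, with a percentile of 0.01, changes the background and not the kind of scaling. A second list of inflammatory genes argues against a weaker response only for its 5 detected members of 36 written. Their median deviation from the mean of the other arrays was 0.022, and the interval (-0.146 to 0.152) spans the lowest and highest of them. So few genes cannot decide on a weaker inflammatory response in general, which stays open. Chance among the 44 pairs stays open: 0.0264 pairs were expected as far out, with genes taken as independent, but 0.346 of the 36 pairs left without replicate 4, and 0.211 and 0.0792 of the 33 pairs left without replicate 3 and without replicate 1. A difference of culture 2 limited to the cytokine and mediator list stays open too, and no test here separates it from handling of that culture.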

How the results depend on the processing

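Scaling by all gene probes, keeping all spots, genes on probes printed 10 times and the restrictions of the spot test to detected probes or to a range over 2-fold were added after the results were seen, and the cause of a change was not tested unless given. The number of probes well above background on all 4 arrays was 5991 under the negative control rule, against 3208, and 3217 to 3972 without each replicate in turn. Detected genes in each fixed list summed to 136 under that rule, against 86, and to 86 to 101 without each replicate. The median SD across replicates, 0.241, was 0.290 after quantile normalization, 0.456 without scaling, 0.167 with normexp, 0.851 scaled by all gene probes, 0.551 without a filter on dim probes, 0.166 for bright genes, 0.184 for probes printed 10 times and 0.192 to 0.254 without each replicate. In the same order, genes over 2-fold between highest and lowest replicate numbered 542, 1027, 39, 1806, 11906 (of 16419), 9 (of 384), 23 (of 386) and 90 to 279, against 297 (15.3%). Under the other detection rules, added for this count after the results were seen, it was 1284 of 3570 genes (36.0%) with negative controls and 623 of 2538 (24.5%) with at least 3 of 4 arrays. The median pairwise correlation of arrays, 0.956, was 0.866 without a filter, 0.980 for probes printed 10 times and 0.929 to 0.975 without each replicate. Probes differing between arrays beyond spot noise numbered 525 among detected probes and 511 with a range over 2-fold, fewer by construction, and 915 to 1046 without each replicate, against 1093. They numbered 760 after quantile normalization, 1301 without scaling, 1276 scaled by all gene probes and 1158 with normexp. The 511 were 18 without replicate 4, 253 without replicate 1, 283 after quantile normalization, 9 with normexp and 932 scaled by all gene probes. Both the 1093 and the 511 include probes at background. All values scaled by all gene probes rest on a percentile near background, as given above. The correlation of deviations of probes of one gene, 0.502, was 0.571 after quantile normalization, 0.914 without scaling, 0.432 with normexp, 0.983 scaled by all gene probes, 0.827 without a filter, 0.567 for bright genes and 0.510 to 0.663 without each replicate. Random pairs of different genes had -0.006 in the main setting, 0.163 after quantile normalization, 0.793 without scaling, 0.106 with normexp, 0.962 scaled by all gene probes, 0.723 without a filter and -0.006 for bright genes. Fixed lists with unusual spread numbered 2 without scaling, 2 with normexp, 1 scaled by all gene probes, 3 without a filter, 1 with the mean of probes and 1 to 2 without each replicate, against 0. List and array pairs with unusual shift numbered 8 with normexp, 2 for bright genes and 4 to 7 without each replicate, against 5. The shift relative to matched random lists of sterol and lipid handling, replicate 3, turned to 0.17 without a filter. Of the other values of these shifts under settings that can move them, which leaves out no scaling and scaling by all gene probes, 34 stayed outside the central range and 9 moved inside it in the same direction. The dimmer genes, nearer to background, had a median SD of 0.30 against 0.195 for the brighter ones, and the cause was not tested. No paired analysis was possible because there is 1 group.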

Other observations

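Gene families outside the fixed lists, chosen after the data were seen, describe the exposed cells further. Ribosomal protein genes were detected in 74 of 83 cases (89.2%) and genes of the respiratory chain and ATP synthase in 62 of 73 (84.9%). Proteasome subunits were detected in 27 of 37 cases (73.0%) and subunits of the vacuolar proton pump in 8 of 21 (38.1%). Translation initiation factors and related genes, taken by the symbol prefix Eif, were detected in 20 of 48 cases (41.7%). Eif2ak1 and Eif4ebp1 are among these and are not initiation factors themselves. Genes of the rat MHC, named RT1, were detected in 12 of 42 cases (28.6%). All 6 shares were above that of all named genes by a two-sided Fisher's exact test, with adjusted p between 4.2e-58 and 0.0035. Chaperonin subunits were detected in 3 of 9 cases (adjusted p = 0.081, Fisher's exact test). None of 1092 olfactory receptor genes was detected (adjusted p = 1.4e-61, Fisher's exact test), and 1 of 46 keratin genes was (adjusted p = 0.043, Fisher's exact test). Detected ribosomal protein genes had a median SD of 0.170 over the 4 cultures, at percentile 70.9 of matched random lists, and proteasome genes 0.184, at percentile 11.9.

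On probes printed 10 times, several further genes ranged over 2-fold between arrays, chosen here after their values were seen. In replicate 4, Rrm2, a subunit of ribonucleotide reductase, lay at -1.33 against -0.15, -0.78 and -0.71, Cdca3 at -2.04 against -0.92, -1.22 and -1.16, and the sterol synthesis gene Msmo1 at -2.57 against -1.32, -1.48 and -1.65. The glutathione peroxidase gene Gpx1 lay at -0.81 there against 0.04, 0.10 and 0.32. All 3 probes of the nucleolar gene Npm1 printed 10 times were highest in replicate 3, the brightest of them at -0.73 against -1.34, -1.82 and -1.84 in replicates 1, 2 and 4.

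Activation of p53 in culture 4 is a hypothesis for the higher Cdkn1a level there. A second list of p53 targets had 5 detected genes. Their median deviation in replicate 4 from the mean of the other arrays was -0.21, with an interval from -1.96 to 0.79. It lay at percentile 42.4 of random lists (-0.18). The median was past the bound of 0.1 set beforehand against this hypothesis. It is left open because the interval, added after the value was seen, is wide and only 5 of 24 targets were measurable. Btg1, at a deviation of -1.96, had been seen before the list was written.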
